A study of Homo sapiens with 7 samples.

How the data were processed

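Total RNA from LNCaP and LTAD prostate cancer cells was labelled with biotin and hybridised to Affymetrix whole-transcript arrays, 1 array per group, per the labels' protocols. The deposited values are log2 expression values per probe set, made with Affymetrix Expression Console and RMA per the submitters' processing notes, which give no versions. RMA as commonly run corrects background, quantile-normalises the arrays and summarises probes on a log2 scale, and which arrays were normalised together is not given in the sources used here. The scale was checked on the values: they ran from 1.65 to 14.3 over the 7 arrays, with near-equal medians, as log2 intensities do, and were not centred per gene. The values carry no detection call, so low expression cannot be told from background. Quantile normalisation makes the arrays' distributions nearly equal and would hide a shift of all genes in one direction.

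The file held 33297 probe sets. In the probe table used here, which is GEO's platform annotation, 19460 had 1 gene symbol, 1754 had several and 12083 were not listed and are unnamed here; only probe sets with 1 symbol were used, and 19429 of these matched the RefSeq gene table of GRCh38.p14 by Entrez number, with 0 symbols changed. Genes without such a probe set were not analysed here. After leaving out 411 probe sets of small RNAs, each gene was represented by the probe set with the highest mean, which left 18024 genes, 761 of them with more than 1 probe set. Gene spans came from the same RefSeq table and cover introns; the genome build of the array design is not used, and no coordinates are given.

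Groups were taken from the sample titles. The labels do not say whether the arrays came from separate cultures, so p-values measure only the spread between these arrays. The LNCaP arrays also carry a control siRNA label although their titles name no transfection. Each pair of arrays was compared by the difference of log2 values, with no test. A gene was counted as 2-fold higher or lower at a log2 difference of at least 1, when the higher of its pair of values reached its array's median over the kept genes. The additive model was fitted with lmFit and eBayes in limma 3.58.1 (R 4.3.3) on 9528 genes at or above the array median in at least 2 arrays. Its 5 coefficients were a base level, cell line, DHT, No.10-3 and siPSF, leaving 2 residual degrees of freedom; departures from additivity enter the residual. The median residual SD was 0.0821 on the log2 scale. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05.

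On simulated arrays with 200 changed genes among 9528, averaged over 20 repeats, the model recovered 87.4% of DHT changes, 96.9% of No.10-3 changes and 51.0% of siPSF changes of 0.5 on the log2 scale, and 99.8%, 100% and 99.2% of changes of 1. Of the genes called, 8.25% were unchanged for DHT, 8.44% for No.10-3 and 8.24% for siPSF, which is above the nominal 5%; the cause was not tested. In unchanged simulated pairs a mean of 2.14 genes passed 2-fold. Of 100 unchanged simulated lists 97 lay inside the percentile limits, and of 100 lists shifted by 0.3 on the log2 scale, 100 lay above them. These lists were drawn at random from genes with independent noise. They do not show how often real lists, whose members move together, fall outside the limits without a change. The simulated effects were equal in every background, and the noise was independent, with a spread already moderated by eBayes. The recovered shares therefore do not give the power on the real arrays, where departures from additivity enter the residual. There, PRSS1 (1.19) and GPNMB (1.02) missed the threshold for No.10-3, at an adjusted p of 0.0521 in limma.

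The comparisons, the model, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined. There were 33 lists, for androgen response, paraspeckles and splicing, cell cycle and DNA repair, stress responses, lipid, energy and polyamine metabolism, interferon and inflammation, histones, ribosomes, long noncoding RNAs, and markers of epithelial, neuroendocrine, stromal, endothelial and leukocyte cells. Each list's median was placed among medians of 10000 random lists matched on mean expression in 20 bins, and percentiles in the extreme tails, 2.5% at each end, were taken as outside the random range. Named genes were SFPQ, NONO, PSPC1, KLK3, ACTB and GAPDH in every comparison, the 10 counted genes with the largest positive and the 10 with the largest negative difference in each comparison, up to 4 members per list with the largest absolute difference, and the 10 genes with the smallest adjusted p per effect. The correlation of comparisons that share the siControl array was set beside 100 simulated draws of unchanged arrays. Alternatives were a 1.5-fold threshold, no level filter and the 75th percentile as level, centring, quantile and cyclic loess normalisation, the mean of all probe sets of a gene, small RNAs kept, and for the model each array left out in turn, interaction terms, a trended robust prior and the LNCaP arrays alone.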

Results

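Gene expression was measured on 7 whole-transcript microarrays of total RNA from human prostate cancer cells, with 1 array in each of 7 groups. LNCaP is a prostate cancer line that responds to androgen, and 4 LNCaP arrays crossed the androgen dihydrotestosterone (DHT, 10 nM for 24 h) or its vehicle with the compound No.10-3 (48 h) or no compound. LTAD cells are prostate cancer cells kept in medium whose serum had been stripped of steroids with charcoal, and 3 LTAD arrays came from cells given a control siRNA, an siRNA against PSF (siPSF), or the control siRNA together with No.10-3. PSF is the protein of the SFPQ gene, an RNA-binding protein of the splicing machinery and of paraspeckles, and the series describes the compound as a small molecule that interacts with PSF. The siRNAs were used at 10 nM, and the dose of No.10-3 is not given in the sources used here. The median log2 expression over all probe sets lay between 5.95 and 6.04 on every array. No group had a replicate, so no difference between a pair of arrays has a replicate check or a p-value, and the small number of arrays limits the precision of every value. The percentile beside a list's median is its place among 10000 random gene lists of the same size matched on expression, and it describes these arrays only. The arrays carry no detection call, so where the lower value of a pair lies well below the median of the kept genes, 6.76 to 6.82, the size of the fold is uncertain and can understate the difference.

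The siRNA target was examined first. SFPQ stood at 10.91 on the log2 scale in the LTAD siControl array and at 9.46 in the siPSF array, a 2.72-fold lower level. With No.10-3 SFPQ differed by -0.20 in LTAD, by -0.11 in LNCaP with vehicle and by -0.33 in LNCaP with DHT. Among the partners of PSF in paraspeckles, PSPC1 was 2.22-fold higher in the siPSF array (8.97 against 10.12), and NONO differed by 0.07. PSPC1 differed by 0.02 and -0.09 with No.10-3 in the LNCaP pairs, and stood at 8.97 with and without it in LTAD. The controls ACTB and GAPDH differed by 0.10 and 0.03 between the siPSF and siControl arrays. In an additive limma model over the 7 arrays, the siPSF effect on SFPQ was -1.45 ± 0.11 (SE, 1 siPSF array, adjusted p = 0.0116), with the spread taken from the other arrays.

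**Figure D1:**
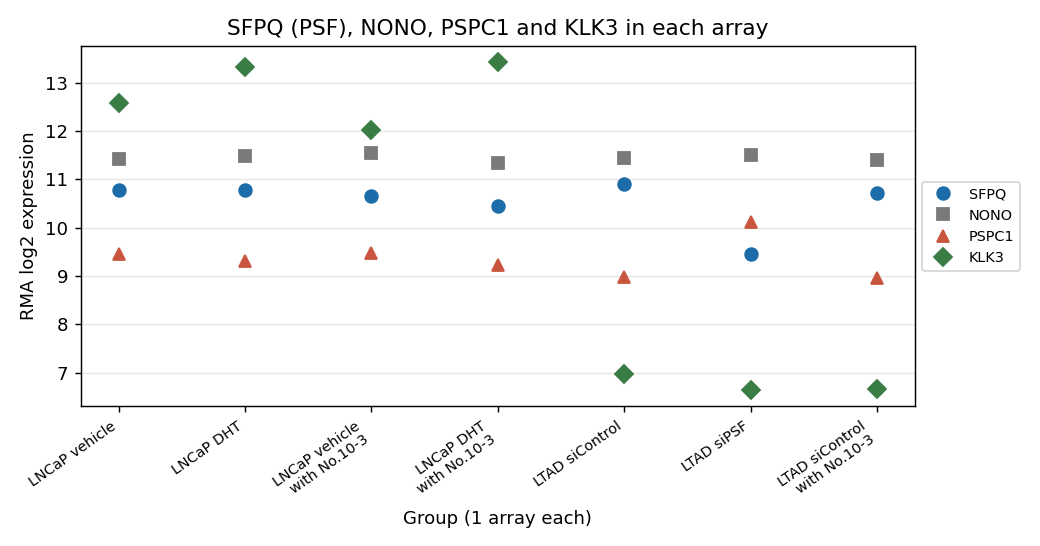
RMA log2 expression (vertical axis) of SFPQ, NONO, PSPC1 and the androgen target KLK3 in each of the 7 groups, 1 point per gene and array, with no error bars because each group has 1 array. SFPQ lies lowest, at 9.46, in the LTAD siPSF array, where PSPC1 lies highest, at 10.12, while KLK3 lies at 12.02 or above in the LNCaP arrays and at 6.98 or below in the LTAD arrays.

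The comparison of DHT with vehicle in LNCaP asked which genes respond to androgen. TARP, a T-cell receptor gamma transcript expressed in prostate cells, was 12.5-fold higher with DHT, and PGC, the gene of the protease precursor progastricsin, was 9.11-fold higher. CHRNA2, a nicotinic receptor subunit, was 7.14-fold higher, and the kallikrein KLK2 and the prostate solute carrier SLC45A3 were 4.78-fold and 4.28-fold higher. ELOVL7, a fatty acid elongase, was higher by 2.06 on the log2 scale, followed by PMEPA1 (1.98), CENPN (1.89), ELL2 (1.82) and GPR158 (1.77). KLK3, which encodes prostate-specific antigen, stood at 12.57 with vehicle and 13.33 with DHT, 1.68-fold higher. On the other side, SLC22A10 (-1.96), the opioid receptor gene OPRK1 (-1.95), MID1 (-1.84), DDC, the enzyme of dopamine and serotonin synthesis (-1.70), SLC44A1 (-1.58), DAPK1 (-1.58), NIPSNAP3A (-1.57), ADD3 (-1.48), TRPS1 (-1.45) and the androgen-glucuronidating enzyme UGT2B17 (-1.32) were lower. TARP and PGC started from low levels, 4.68 and 5.31, so the sizes of their folds are uncertain. TARP had 3 probe sets on the array, of which 1, at a low mean of 4.36, differed by -0.06. The others gave identical values, so they are not separate measurements.

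All 41 measured members of the androgen-induced list were higher with DHT, with a median difference of 0.76 (percentile 100), and 18 of them by at least 2-fold, among them KLK2 (2.26), and STEAP4 (2.68) and HPGD (2.29) from low vehicle levels of 3.29 and 3.27 that leave the size uncertain. The median of the 12 androgen-repressed genes was -0.62 (percentile 0), with SI at -1.83, while TMEFF2 of that list was higher by 1.45. Genes of DNA replication and S phase were also higher, with a median of 0.73 over 44 genes, for example CDC6 (1.72), MCM10 (1.24), DTL (1.21) and CLSPN (1.16). Cholesterol synthesis genes had a median of 0.73 over 19 genes, with HMGCS1 at 1.27, IDI1 at 1.05 and INSIG1 at 0.98. Fatty acid synthesis genes had a median of 0.33 (FASN 1.12, ELOVL5 1.02), polyamine synthesis genes 0.54 (ARG2 0.87, SMS 0.85) and ribosome biogenesis genes 0.38, with 31 of 31 members above 0. The homologous recombination list had a median of 0.48 (EXO1 1.06) and the mitosis list 0.26 (CENPK 0.98, MAD2L1 0.93). Interferon response genes had a median of -0.23 (percentile 0), with IRF9 at -0.68 and BST2 at -0.65, but -0.03 (percentile 18.85) in the DHT pair with No.10-3, and the additive model's median DHT effect was -0.07 with 1 of 15 tested members lower. In all, 63 genes were higher and 32 lower by at least 2-fold among the 9268 genes counted.

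DHT was measured in 2 pairs of LNCaP arrays, without and with the compound, and the additive limma model took its effect as equal in both. At an adjusted p under 0.05, 283 genes rose and 295 fell among 9528 tested, of which 43 and 26 did so by at least 2-fold. The smallest adjusted p, 0.00153, belonged to OPRK1, which fell by 1.98 ± 0.08 (SE), to CHRNA2, which rose by 2.69 ± 0.12, and to ELOVL7, which also rose. HERC3 (1.72), LCP1 (1.45), TMEFF2 (1.40), KCNMA1 (1.33), ST6GALNAC1 (1.74) and ABCC4 (1.60) rose as well, and SLC44A1 changed by -1.45. Of the 31 androgen-induced genes tested, 26 rose, and 28 did when adjusted over the list alone. Of 31 ribosome biogenesis genes, 8 rose, and 16 when adjusted over the list alone, and of 10 polyamine genes 5 rose, and 6 when adjusted over the list alone. No member of the 42 tested S-phase genes passed either adjustment. The S-phase list's median DHT difference was 0.73 without and 0.02 with No.10-3, and this mismatch enters the residual of its genes. The 0 calls therefore do not argue against a DHT difference of these genes without No.10-3. Members of a list move together, so counts over a list alone are no test of the list. The counts depended on single arrays: they were 52 and 29 without the LNCaP vehicle array, 29 and 20 without the LNCaP vehicle array with No.10-3, and 686 and 458 without the LNCaP DHT array with No.10-3.

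With No.10-3 present, the androgen targets still differed between DHT and vehicle. KLK2 was 9.91-fold higher with DHT, SLC45A3 6.72-fold, TARP 6.21-fold, PMEPA1 5.99-fold and KLK3 2.65-fold. The vehicle levels of KLK2 and KLK3 were lower with the compound than without it, KLK2 at 7.83 against 8.65 (-0.81) and KLK3 at 12.02 against 12.57 (-0.55), and with DHT the compound arrays differed by 0.24 and 0.10, so much of the larger DHT difference of these genes lies in the vehicle arrays. STEAP4, a metalloreductase, stood at 3.56 with vehicle and 7.49 with DHT, and with so low a vehicle level the size of its fold is uncertain. The transcription factor SNAI2 was higher by 2.56, followed by CHRNA2 (2.54), CENPN (2.43), PLA2G5 (2.15) and INPP4B (2.02). MID1 (-2.80), OPRK1 (-2.02), SI (-1.98), UGT2B17 (-1.85), CBLN2 (-1.66), SLC22A10 (-1.55), TLL1 (-1.48), TMEM38B (-1.46), RFX3 (-1.39) and MCTP1 (-1.36) were lower. By at least 2-fold, 65 genes were higher and 33 lower among 9259 counted.

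The DHT difference of the androgen-induced list was no smaller with the compound. Its median was 0.94 with No.10-3 against 0.76 without it, and the median change per gene was 0.20 (percentile 100), with a larger difference in 30 of 41 members and a smaller one in 11. PGC was among the 11: its DHT difference was 3.19 without the compound and 1.89 with it. The androgen-repressed list had medians of -0.59 with and -0.62 without No.10-3, and per gene the DHT difference was more negative with the compound in 10 of 12 members, by a median of -0.10. The S-phase list went the other way, with a median DHT difference of 0.02 (percentile 80.6) with No.10-3 against 0.73 without, and a smaller difference in 44 of 44 members. The DHT difference was also smaller in 44 of 47 mitosis genes, 24 of 25 homologous recombination genes and 18 of 19 cholesterol synthesis genes, and larger in 35 of 36 genes of the ATF4 and unfolded protein response, among them DNAJB9 (1.13 with No.10-3) and HERPUD1 (0.80). An interaction term of DHT and No.10-3 in limma, with 1 residual degree of freedom, called 0 of 9528 genes at an adjusted p under 0.05, the smallest adjusted p being 0.0623, and 1382 genes at an unadjusted p under 0.05. Each of the arms of this term is 1 array, and its residual is the mismatch of the No.10-3 difference between LTAD and LNCaP with vehicle, so a deviation of 1 array would move related genes together and the term is no test of a list. Across genes, which are not independent replicates, the DHT differences without and with the compound correlated with r = 0.624.

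**Figure D2:**
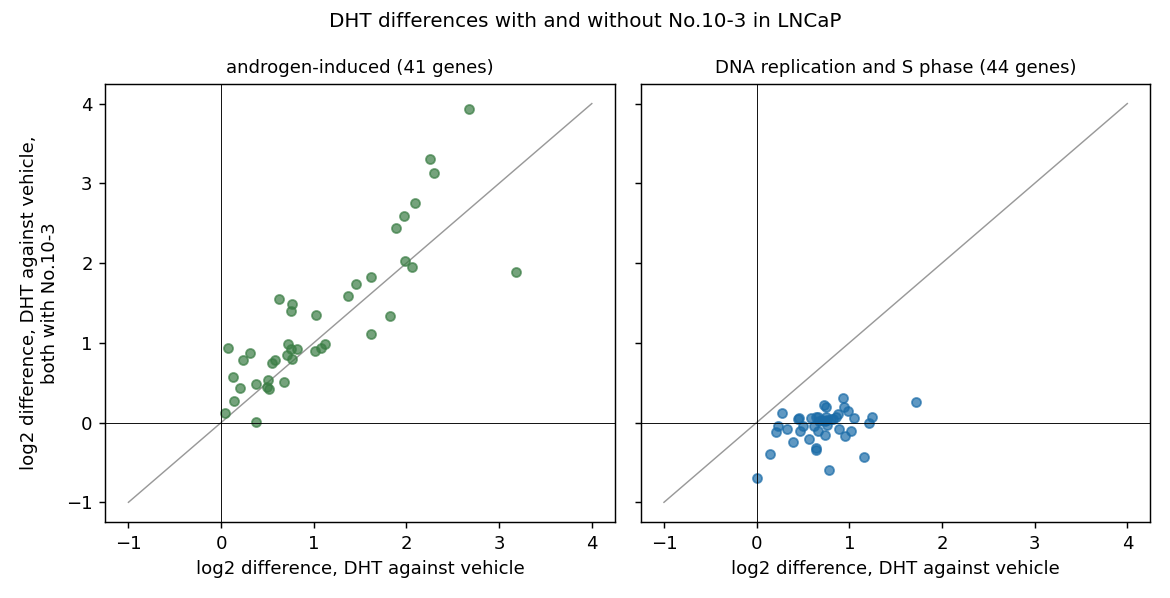
Log2 difference between DHT and vehicle in LNCaP without No.10-3 (horizontal axis) and with it (vertical axis), 1 point per gene, for the 41 androgen-induced genes (left) and the 44 S-phase genes (right); the grey line marks equal differences. The androgen-induced genes scatter around the line with 30 above it, while the 44 S-phase genes lie below it, around a median of 0.02 with the compound.

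The arrays with and without No.10-3 asked what the compound does in each background. In LNCaP with vehicle, the chemokine CCL20 was 3.27-fold higher with the compound, followed by SLITRK6 (1.42), PKIB (1.36), DIO3, the enzyme that inactivates thyroid hormone (1.33), CHAC1, a glutathione-degrading ATF4 target (1.33), CTH, the transsulfuration enzyme (1.25), CD55 (1.19), GPNMB (1.14), and the amino acid transporters SLC6A9 (1.05) and SLC7A11 (1.04). The histone gene H2BC14 was 3.58-fold lower and the replication initiation factor MCM10 2.43-fold lower, with DAPK1 (-1.13), FAM111B (-1.10), PCLAF (-1.10), ESCO2 (-1.08), OR51E1 (-1.05), NCAPH (-1.05), H1-5 (-1.05) and TUBA4A (-1.02) next. The S-phase list had a median of -0.51 and the mitosis list -0.50 (both percentile 0), with 42 of 44 and 46 of 47 members lower in the compound array. Ribosome biogenesis genes had a median of -0.20 and cholesterol synthesis genes -0.21, and the ATF4 and unfolded protein response had a median of 0.31 (percentile 100), with ASNS at 1.02 and PSAT1 at 0.95. By at least 2-fold, 12 genes were higher and 11 lower among 9210 counted.

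In LNCaP with DHT the differences with No.10-3 were larger. CHAC1 was 6.94-fold higher, DDIT3, which encodes the stress factor CHOP, 4.65-fold, and SLC7A11, a cystine transporter, 4.22-fold, with SLC6A9 (1.87), SLC1A4 (1.82), PCK2 (1.79) and ASNS (1.74) also higher. CD55 (2.15), BEST1 (1.81) and the interferon-induced gene IFI44L (2.31) were higher too. H2BC14 was 6.15-fold lower, MCM10 5.47-fold and FAM111B 5.35-fold, and CLSPN (-2.24), TM4SF1 (-2.22), H1-5 (-2.21), DTL (-2.14), EXO1 (-2.13), ESCO2 (-2.06) and MND1 (-2.03) followed. All 44 S-phase genes were lower, with a median of -1.20 and 31 of them by at least 2-fold. All 47 mitosis genes were lower, with a median of -0.96 and 22 by at least 2-fold, among them CDK1 (-1.66), ANLN (-1.63) and MKI67 (-1.58). The homologous recombination list had a median of -0.85, replication-dependent histones -0.45, cholesterol synthesis -0.57 (EBP -1.31, HMGCS1 -1.03), ribosome biogenesis -0.37, heat shock -0.33 (HSPH1 -0.81) and the spliceosome -0.30, all at percentile 0. The ATF4 list had a median of 0.66 (percentile 100), with 10 of 36 members at least 2-fold higher, and interferon response genes 0.21 (percentile 99.99), with IFIT2 at 1.39 and OAS1 at 1.20. Stromal markers had a median of 0.20 (percentile 99.2) in the same pair, with 15 of 18 above 0, though only 3 of them passed the model's level filter. The interferon and stromal lists lay below 0 with DHT (-0.23 and -0.22), a comparison that shares the LNCaP DHT array. The androgen-induced list had a median of 0.14 (percentile 99.97), with STEAP4 at 1.52, TSC22D3 at 1.34 and PGC at -1.76. In all, 38 genes were higher and 152 lower by at least 2-fold among 9313 counted. In the No.10-3 pairs without the LNCaP DHT array, the interferon median was 0.11 (percentile 99.7) in LNCaP with vehicle and 0.085 (percentile 99.3) in LTAD. The stromal medians there were -0.04 and -0.05. For No.10-3 the additive model called 0 of 15 tested interferon genes over all genes, and 1, lower, over the list alone.

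In LTAD the compound's differences were fewer. GPNMB, a melanosomal glycoprotein, was 2.23-fold higher, DIO3 2.12-fold and BTN3A1 2.04-fold, with PRSS1 (0.86), SMIM14 (0.73), ANKRD20A8P (0.72), CFAP69 (0.70), KIF5C (0.69), PCDHB15 (0.69) and CHST11 (0.68) next. Histone genes led the lower side: H2BC14 was 4.73-fold lower and H1-5 2.75-fold, with H3C2 (-1.27), H3C11 (-1.17), H1-2 (-1.05), H2AC21 (-1.05) and H4C2 (-0.93), besides MTFR2, MCM10 (-0.99) and PCLAF (-0.93). Probe sets of such near-identical histone genes can share sequence, so the member that differed is uncertain. All 44 S-phase genes were lower, with a median of -0.56, and the mitosis list had a median of -0.38 and the histone list -0.35, each at percentile 0. The ATF4 list had a median of -0.02 (percentile 38.1) and cholesterol synthesis genes 0.07 (percentile 98.5). Heat shock genes had a median of -0.04 (percentile 27.7), and the additive model called 0 of 18 of them for No.10-3 by either adjustment. The p53 targets had a median of 0.18 (percentile 100), with CDKN1A, the cell cycle inhibitor p21, at 0.65 and ZMAT3 at 0.54. By at least 2-fold, 3 genes were higher and 6 lower among 9196 counted. The p53 targets also lay above the random range with No.10-3 in LNCaP, at 0.10 (percentile 99.9) with vehicle and 0.12 (percentile 99.6) with DHT. For No.10-3 the additive model called 0 of 25 p53 targets over all genes and 5, all higher, over the list alone.

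Across 9528 genes the No.10-3 differences correlated with r = 0.650 between the LNCaP pairs, 0.485 between LTAD and LNCaP with vehicle, and 0.509 between LTAD and LNCaP with DHT, with no array shared between those pairs; genes are not independent replicates. In the additive limma model over the 3 pairs, H2BC14 fell by 2.24 ± 0.14 (SE) and DIO3 rose by 1.17 ± 0.08, both at an adjusted p of 0.0169, and no other gene passed 0.05 of the 9528 tested, with 2080 at an unadjusted p under 0.05. The next genes were TK1 (-0.93), APOBEC3B (-0.75), GPNMB (1.02), H2BC7 (-0.88) and PRSS1 (1.19), each at an adjusted p of 0.0521, and TUBA1C (-0.78), AURKB (-0.76) and CDCA3 (-0.74) at 0.0625. Adjusted over the list alone, 40 of 42 S-phase genes, 45 of 46 mitosis genes, 13 of 22 homologous recombination genes, 14 of 22 histone genes, 17 of 31 ribosome biogenesis genes and 15 of 59 spliceosome genes fell, against 1 histone gene and no other member of these lists over all genes. Members of a list move together and no correction was made over the 33 lists, so these counts are no test of a list. The model also took the effect as equal in the 3 pairs, where the S-phase medians were -0.51, -1.20 and -0.56. In LNCaP alone, where the effect was taken as equal with vehicle and DHT, 67 genes rose and 131 fell. Leaving out the LTAD siControl array, or the LTAD siControl array with No.10-3, is the same fit for No.10-3 and gave the same counts. Leaving out either LNCaP DHT array gave 29 and 121 genes, and leaving out either LNCaP vehicle array gave 0 and 1. An interaction of No.10-3 with the cell line called 0 genes in limma, with 356 at an unadjusted p under 0.05. Its 1 residual degree of freedom is the mismatch of the No.10-3 difference between LNCaP with vehicle and with DHT. The 0 calls therefore do not argue against a difference between the lines.

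**Figure D3:**
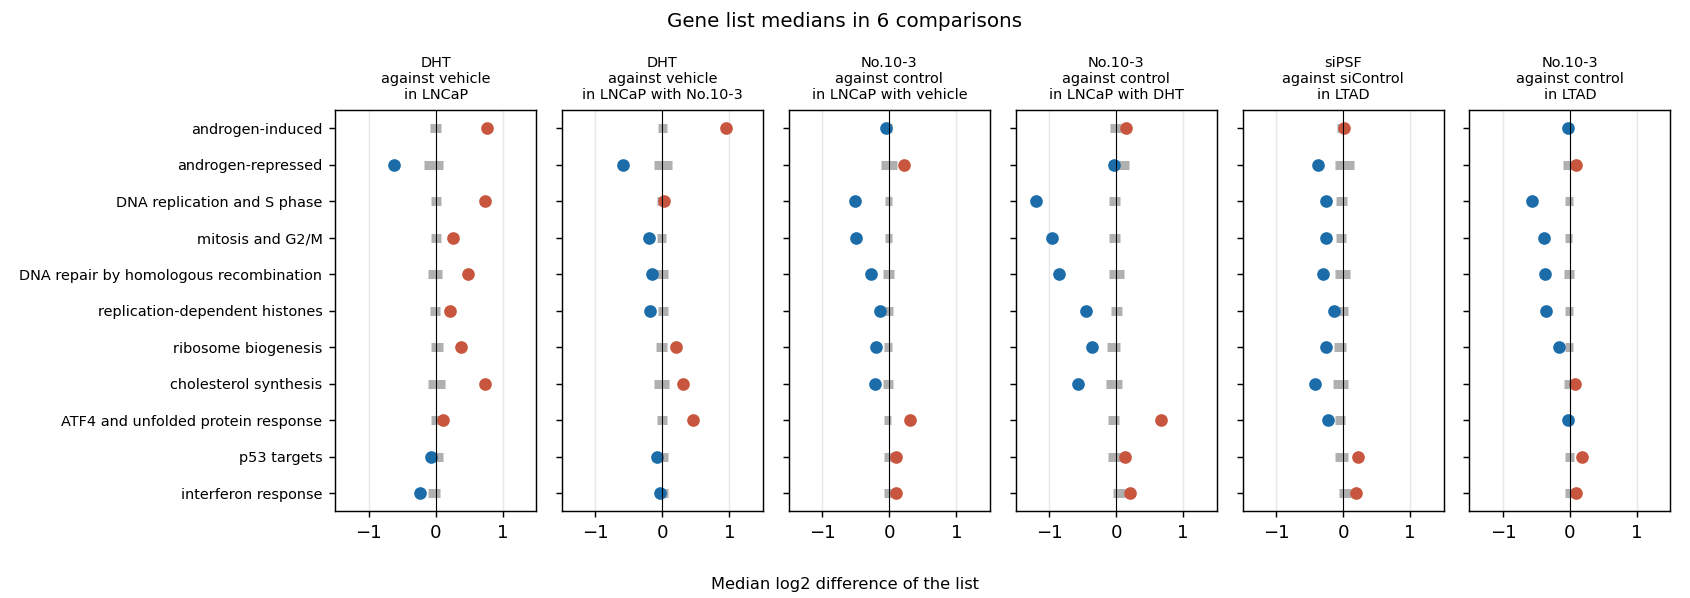
Median log2 difference (horizontal axis) of 11 of the fixed gene lists in 6 comparisons, 1 panel each; points are list medians (red above 0, blue below) and grey bars the range of medians of 10000 matched random lists without the extreme tails at each end. The S-phase point moves from 0.73 with DHT to 0.02 with DHT in the presence of No.10-3, and lies at -0.51, -1.20 and -0.56 with No.10-3 in LNCaP with vehicle, LNCaP with DHT and LTAD.

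The LTAD siPSF and siControl arrays asked which genes depend on PSF. The class 3 semaphorin SEMA3C was 4.01-fold lower in the siPSF array, NAALADL2 3.65-fold, CMSS1 3.18-fold, the kinase gene PRKCA 3.14-fold, and the synaptic adhesion gene NLGN1 3.11-fold, and ANK3 (-1.59), TENM2 (-1.58), the G protein subunit GNAQ (-1.49) and ACTR3C (-1.46) followed. On the higher side stood OASL, an interferon-induced gene (3.52-fold), AGT, which encodes angiotensinogen (2.65-fold), IFIT1 (2.62-fold), the transcription factor JUN (2.25-fold), PSPC1, and SLC44A4 (1.06), followed by KIF27, PLEKHH1 (0.97), MYLIP (0.93) and UBE2Q2P1 (0.92). By at least 2-fold, 7 genes were higher and 71 lower among 9304 counted. In the additive limma model the siPSF coefficient was above 0 for 42 genes and below 0 for 239 at an adjusted p under 0.05, 7 and 70 of them by at least 2-fold. The single siPSF array fits its own coefficient, so no residual measures its spread, and these calls, their SE and their p-values rest on the untested assumption that it varies like the others. The coefficient was -1.93 ± 0.11 (SE) for NAALADL2, -1.62 for NLGN1 and -1.57 for ANK3, each at an adjusted p of 0.00922. CMSS1 (-1.62), ZCCHC7 (-1.34), PPFIA2 (-1.42), SCFD2 (-1.39), FAF1 (-1.22) and MBD5 (-1.31) followed at 0.0116. The counts were 10 and 102 without either LNCaP vehicle array, 161 and 649 without either LNCaP DHT array, 15 and 65 without the LTAD siControl array, and 27 and 170 without the LTAD siControl array with No.10-3.

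Genes that span a long stretch of the genome were lower in the siPSF array. By the gene spans of the GRCh38.p14 annotation, the 145 genes over 400 kb had a median difference of -0.54, with 46.9% lower and 0 higher by at least 1.5-fold, and the 422 genes of 200 to 400 kb a median of -0.25, with 21.6% lower. Without the level filter the median of genes over 200 kb was -0.09 in place of -0.32. The medians were -0.07 for 100 to 200 kb, -0.03 for 30 to 100 kb, -0.02 for 10 to 30 kb and 0.01 for genes up to 10 kb. Of the genes lower by at least 2-fold in these classes, 28 were over 400 kb and 27 were between 200 and 400 kb. Across 9521 genes with a span, Spearman's rho was -0.171, a size not particular to siPSF: rho was -0.178 for DHT with No.10-3, -0.140 for LTAD against LNCaP and 0.143 for No.10-3 in LNCaP with vehicle. For the 567 genes over 200 kb the median was -0.32 with siPSF, and with No.10-3 it was 0.02 in LTAD, against the same siControl array, 0.05 in LNCaP with vehicle and 0.04 in LNCaP with DHT. It was -0.05 for DHT, -0.09 for DHT with No.10-3 and -0.10 for LTAD against LNCaP.

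**Figure D4:**
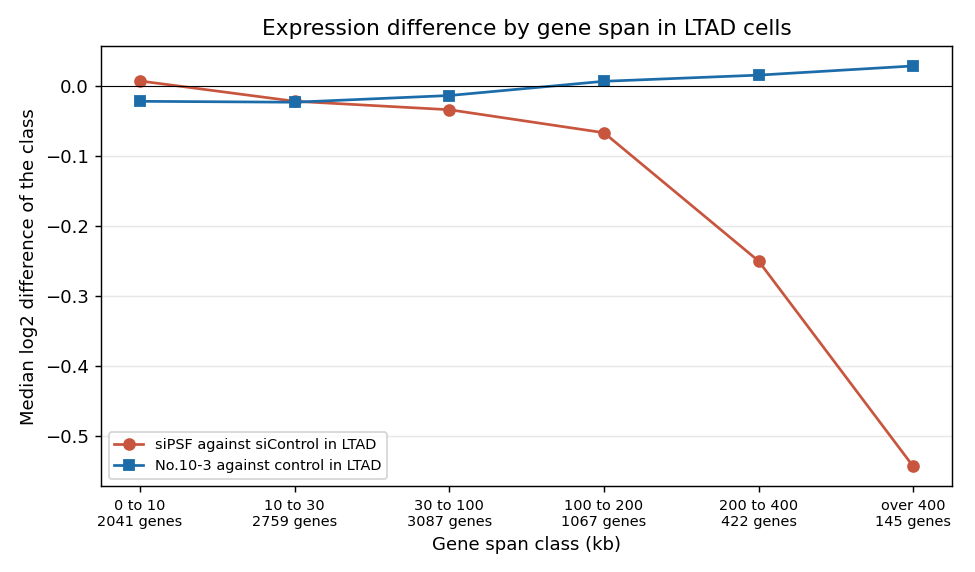
Median log2 difference (vertical axis) of genes in 6 classes of gene span in kb (horizontal axis, with the number of genes in each class), for siPSF (circles) and No.10-3 (squares) against the same LTAD siControl array. The siPSF medians go from 0.01 in the class up to 10 kb to -0.54 over 400 kb, and the No.10-3 medians lie between -0.02 and 0.03.

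Among the gene lists, cholesterol synthesis had a median of -0.41 in the siPSF array (MSMO1 -0.98, SQLE -0.82), the S-phase and mitosis lists -0.25 each (CDC6 -0.65, ANLN -1.27), homologous recombination genes -0.30, ribosome biogenesis genes -0.25 (DDX10 -0.78) and the ATF4 list -0.22 (percentile 0). Interferon response genes had a median of 0.20 (percentile 100), with 6 of 34 at least 2-fold higher, among them IFIT2 (1.41), IFIT3 (1.40) and the chemokine CXCL10 (1.39), and p53 targets 0.22 (CDKN1A 0.83, TP53I3 0.69). Leukocyte markers also had 0.22 (percentile 99.7), with 14 of 15 above 0, though only 1 of them passed the model's level filter. Metallothioneins had a median of 0.42 (MT2A 0.60, MT1X 0.54). The androgen-induced list had a median of 0.01 (percentile 71.2), and KLK3 differed by -0.34. The androgen-repressed list had a median of -0.38, with the neurotensin gene NTS at -1.81. The paraspeckle list had a median of 0.07 (percentile 97.1) and the spliceosome list -0.07 (percentile 18.7). A deviation of the single siPSF array would move related genes together, so the limma counts that follow are no test of a list. The siPSF coefficient passed the threshold above 0 for 2 of 15 tested interferon genes over all genes and over the list alone. It passed below 0 for 2 of 31 ribosome biogenesis genes over all genes and 7 over the list alone, for 2 of 22 homologous recombination genes by either adjustment, and for 2 of 18 cholesterol synthesis genes over the list alone only. Of 7 tested metallothioneins, 4 passed above and 1 below 0 over the list alone and 0 over all genes. For the S-phase, mitosis and ATF4 lists limma called 0 of 42, 0 of 46 and 0 of 33 members over all genes and also when adjusted over the list alone, with 2058 of all genes tested at an unadjusted p under 0.05. The ATF4 list's median siPSF effect in the model was 0.0075 over the tested members, against the median of -0.22 in the pair of arrays.

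The siPSF and No.10-3 differences were set side by side because both were directed at PSF. In LTAD they correlated across genes with r = 0.281, while unchanged arrays sharing the siControl array gave a simulated r of 0.502. The covariance was 0.0137 against 0.0152 simulated, so that the difference, -0.00148, lay below 0. The simulated spread was the model's residual, which also holds departures from additivity, so the simulated covariance may be too large. The simulation therefore does not decide whether siPSF and No.10-3 share more in LTAD than the control array. With LNCaP, where no array is shared, r was 0.137 with vehicle, or 0.0876 without the level filter, and 0.216 with DHT. Of genes lower by at least 1.5-fold, 39 were shared by siPSF and No.10-3 in LNCaP with DHT, where independent lists would share 14.2, and of those higher 12, against 1.38. In LNCaP with vehicle 12 lower genes were shared against 3.61, and in LTAD 12 against 2.83, part of which may come from the shared control array. The S-phase, mitosis and ribosome biogenesis lists had medians below 0 with siPSF and in each No.10-3 comparison, and the p53 and interferon lists medians above 0. In LTAD siPSF and No.10-3 are measured against the same siControl array, so a shared sign there would also come from that array reading high or low for these lists. For siPSF the model called 0 of 42 S-phase, 0 of 46 mitosis, 2 of 31 ribosome biogenesis, 1 of 25 p53 and 2 of 15 interferon members over all genes. The residual in these counts also holds departures from additivity, so a count of 0 does not argue against a difference. The ATF4 list had -0.22 with siPSF in the pair of arrays, and with No.10-3 -0.02 in the same LTAD cells (percentile 38.1) and 0.31 and 0.66 in LNCaP. Its siPSF effect in the model was 0.0075. Because the model takes the No.10-3 effect as equal in both lines, that value does not check the pair. For No.10-3 the model called 0 of 33 ATF4 members over all genes, and 2 higher over the list alone, with a median effect of 0.32.

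The LTAD siControl and LNCaP vehicle arrays differ in cell line and serum together, and whether the LNCaP cells were transfected, as the LTAD cells were, is uncertain because they carry a control siRNA label. KLK3 was 48.2-fold lower in LTAD (12.57 against 6.98). MMP16, a membrane metalloprotease, stood at 10.57 in LNCaP and 3.74 in LTAD, DENND1B at 8.81 and 3.79, the kinase gene RPS6KA6 at 9.05 and 4.17, and TOX3 at 9.72 and 4.91, and at such low LTAD levels the sizes of their folds are uncertain. BCHE (-4.68), ADAMTS1 (-4.68), the olfactory receptor OR51E1 (-4.64), ATP1B1 (-4.58) and GASK1B (-4.39) were lower as well. S100A16 was 15.2-fold higher, with BNC2 (3.89), TRIB2 (3.86), DOK6 (3.85), IGFBP5 (3.77), the cancer-testis genes SAGE1 (3.70) and PASD1 (3.70), S100A14 (3.51), SRPX (3.42) and ACOX2 (3.31) next. By at least 2-fold, 153 genes were higher and 213 lower among 9397 counted. The androgen-induced list had a median of -0.38 and interferon response genes -0.52 (IFI44 -3.01), both at percentile 0. Mitosis genes had a median of 0.68, S-phase genes 0.54, ribosome biogenesis genes 0.46 and the ATF4 list 0.45 (ASNS 1.41), each at percentile 100. The mesenchymal filament gene VIM was higher by 2.45 and NTS by 3.27.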

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

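The tests of a general block of the DHT response, of the LNCaP DHT array, of cell line against growth medium and of the splits of the arrays were chosen only after the result was seen.

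These results stood apart because values for DHT or No.10-3 differed between backgrounds on these single arrays. By the interaction of DHT and No.10-3 in limma, adjusted over the list alone, the term was below 0 and past the threshold for 39 of 42 S-phase genes, 29 of 46 mitosis genes, 12 of 22 homologous recombination genes and 9 of 18 cholesterol synthesis genes, and above 0 for 17 of 33 ATF4 and unfolded protein response genes. Each arm of the term is 1 array and its residual is only the mismatch of No.10-3 between LTAD and LNCaP with vehicle, so these counts do not show that the DHT response of a list changed. Over all genes the interaction called 0 in limma, with 1382 at an unadjusted p under 0.05.

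Other list medians had opposite signs, and for these medians the difference was not tested. With DHT the mitosis list had a median of 0.26 without No.10-3 and -0.20 with it, the homologous recombination list 0.48 and -0.16, and replication-dependent histones, such as H1-5, 0.22 and -0.18. With No.10-3 cholesterol synthesis genes had medians of -0.21 and -0.57 in LNCaP with vehicle and with DHT and of 0.068 in LTAD, and glycolysis and hypoxia genes -0.14 and -0.28 in LNCaP and 0.079 in LTAD.

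The DHT difference of S-phase genes such as CDC6, MCM10 and DTL was smaller with No.10-3. A general block of the DHT response is argued against by the androgen-induced list, whose DHT difference was larger with the compound by a median of 0.20. The LNCaP DHT array reading high for S-phase genes cannot be told apart from a change of the DHT response, because 1 LNCaP array holds DHT without the compound. The pairs that do not use that array had S-phase medians of -0.51 in LNCaP with vehicle and -0.56 in LTAD, which does not test the DHT response. Fewer cells in S phase with the compound is a candidate explanation that these arrays do not test.

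Genes of the ATF4 response such as CHAC1, ASNS and SLC7A11 were higher with No.10-3 in LNCaP, and the list's median lay near 0 in LTAD. A higher starting level in LTAD may leave less room for a difference, but 6 members that started no higher in LTAD had a median of 0.011 there and 0.09 in LNCaP with vehicle, both inside the range of matched random lists, so the test decides nothing. Cell line or growth medium cannot be told apart either, since each medium was used for 1 cell line. The interaction of No.10-3 with the cell line in limma does not decide whether the lines differ. Each of its LTAD arms is 1 array, and its residual is only the mismatch of the No.10-3 difference between LNCaP with vehicle and with DHT.

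The additive model called 2 genes for No.10-3, and the highest count of the other splits of the 6 arrays into 3 and 3 was 0. With 1 of 10 splits calling as many genes, the splits are too few for a share under 0.05.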

How the results depend on the processing

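No paired analysis was possible because each group has 1 array, so no replicate numbers pair cultures; the additive model takes DHT and No.10-3 within backgrounds. Of the alternative values of the counts, the correlations, the span results and the androgen-induced DHT response, 135 stayed the same and 83 moved. Of those of gene list medians, 1102 stayed within the spread of random lists, 45 moved beyond it and 1 changed sign, and of those of named genes 695 stayed and 21 moved. The luminal marker list changed sign with DHT, from 0.17 to -0.10, when only members at the array median in at least 1 array were kept; fewer genes entered. Centring, quantile and loess normalisation moved the split of higher against lower genes by at most 4.97 points. In the additive model 0 called genes changed sign under the alternatives run for it.

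With a 1.5-fold threshold, which is laxer, the counts of higher and lower genes became 322 and 186 for DHT, 211 and 170 for DHT with No.10-3, 41 and 96 for No.10-3 in LNCaP with vehicle, 183 and 406 with DHT, 21 and 80 in LTAD, 70 and 329 for siPSF, and 584 and 595 between the lines. With the 75th percentile as level, fewer genes were counted: 19 lower for DHT, 20 lower for DHT with No.10-3, 4 higher for No.10-3 in LNCaP with vehicle, 21 and 81 with DHT, 0 higher in LTAD, 3 and 32 for siPSF, and 66 and 121 between the lines. With no level filter more were counted: 50 lower for DHT with No.10-3, 17 higher for siPSF, and 8 and 12 for No.10-3 in LTAD.

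In the additive model, the interaction of DHT and No.10-3 gave 686 and 458 genes for DHT, 29 and 121 for No.10-3, and 161 and 649 for siPSF. For No.10-3 and siPSF that is the same fit as leaving out either LNCaP DHT array, not a separate alternative. The interaction of No.10-3 and cell line gave 67 and 131 for No.10-3, as did the 4 LNCaP arrays alone, which is the same fit for No.10-3, and 27 higher for siPSF. The trended robust prior gave 33 and 85 for No.10-3 and 68 higher for siPSF, and quantile normalisation 13 and 29 for No.10-3 and 73 higher for siPSF. No level filter gave 156 and 150 for DHT, 2 lower for No.10-3, and 17 and 131 for siPSF. The cause was not tested for these. Asking also for a 2-fold effect, which is stricter, left 43 and 26 for DHT and 7 and 70 for siPSF. Leaving out 1 array at a time, which leaves fewer arrays, gave 29 to 686 higher and 20 to 458 lower for DHT, 0 to 67 and 1 to 131 for No.10-3, and 10 to 161 and 65 to 649 for siPSF; no siPSF effect exists without its array.

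Without the level filter, the correlation across genes of siPSF with No.10-3 in LNCaP with vehicle was 0.0876 in place of 0.137, and the median siPSF difference of genes over 200 kb was -0.093 in place of -0.32. The cause was not tested. The arrays carry no detection call, so signal near background limits the values of low genes.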

Other observations

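The tests of the siControl array and of other actions of the siRNA were chosen only after the result was seen.

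The lists not described so far had the following medians. The aryl hydrocarbon receptor list holds enzymes of foreign compound metabolism and also other genes, among them AHR, ARNT and SLC7A5. With No.10-3 it had a median of 0.22 in LNCaP with vehicle (percentile 99.99), with CYP1A2 at 0.82 and CYP1A1 at 0.81. The median was 0.16 in LNCaP with DHT (percentile 95.4) and 0.09 in LTAD (percentile 92.9). But the model's median No.10-3 effect over the 4 tested members was 0.041, with 0 called by either adjustment. NRF2 targets had a median of 0.12 with No.10-3 in LTAD (percentile 99.98), with NQO1 at 0.47, 0.08 in LNCaP with vehicle (percentile 99.6) and -0.02 in LNCaP with DHT (percentile 41.7), and the model called 0 of 18 over all genes, and 4 higher and 1 lower over the list alone. Inflammation genes had 0.14 with No.10-3 in LNCaP with vehicle (percentile 99.8), with TRAF1 at 0.65, 0.09 in LNCaP with DHT (percentile 78.4) and 0.01 in LTAD (percentile 58.1), with 0 of 7 tested members called for No.10-3 by either adjustment. Oxidative phosphorylation genes had -0.13 with No.10-3 in LTAD and -0.15 with siPSF (SDHD -0.36 and -0.37), both against the same siControl array. For either effect the model called 0 of 30 of these genes by either adjustment. Glycolysis and hypoxia genes had 0.10 with siPSF (ENO2 0.86), and the model's median effect over the 29 tested members was -0.05. The model takes the No.10-3 effect as equal in both lines, while the list's No.10-3 medians were 0.079 in LTAD and -0.14 and -0.28 in LNCaP. The model value therefore does not check the pair. Apoptosis regulators lay between -0.07 and 0.06, and ribosomal proteins between -0.01 and 0.09. The 4 measured prostate long noncoding RNAs, MALAT1 among them, had a median of -0.01 with siPSF. Steroid receptors and their cofactors had -0.14 with DHT, with NR3C2 at -0.47.

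Among the marker lists, luminal genes had a median of 0.17 with DHT, which turned to -0.10 when only members at the array median in at least 1 array were kept, with MSMB at 0.89 and ACP3 at -0.64. In the DHT pair with No.10-3 the luminal median was 0.01 (percentile 58.6). Basal genes had -0.05 with siPSF (ITGA6 -0.77), neuroendocrine genes -0.07 (CPE -1.20), endothelial genes 0.08 and leukocyte genes 0.22 (LYZ 0.63). Only 3 of 11 basal, 5 of 22 neuroendocrine, 0 of 12 endothelial and 1 of 15 leukocyte members passed the model's level filter. These medians therefore rest mostly on low values. Stromal genes, 3 of 18 of which passed that filter, had -0.22 with DHT (THY1 -0.59) but 0.01 (percentile 53.2) in the DHT pair with No.10-3. Genes of the epithelial to mesenchymal transition had 0.03 with DHT, with SNAI2 at 1.40.

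Genes of long span, such as NAALADL2, NLGN1 and ANK3, were lower in the siPSF array. The siControl array reading high for long genes is argued against by No.10-3 in LTAD, whose median for genes over 200 kb against that same array was 0.018. Low signal of long genes is argued against by the 271 of them at or above the 75th percentile of expression, with a median of -0.34 against -0.09 to -0.02 in matched random sets. Loss of PSF may lower long genes, but another action of the siRNA stays open, since 1 siRNA against PSF was used. A deviation of the single siPSF array for long genes stays open as well, because the No.10-3 comparison does not use that array.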
